A study of Mus musculus with 4 samples.

How the data were processed

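The study measured total RNA of sorted YFP-positive Treg cells from wild-type and Foxp3-restricted Cyld knockout mice, 2 arrays per genotype. RNA was isolated with a column kit and turned into biotin-labelled cRNA by the standard Affymetrix procedure, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array; this follows from the values themselves, which run from 26.6 to 7205. How the authors summarised, background-corrected and scaled the arrays is not given in the sources used here. Array medians between 99.0 and 105 show that the deposited arrays share a scale. No detection call accompanied the values used, and the lowest values stay well above 0, so folds of dim genes are understated and no gene could be called absent.

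Probe sets were named with a platform annotation of 2016. Of 35557 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12147 had none listed; only those with exactly 1 entered the gene comparison. Entrez identifiers of 21698 of them matched a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. No genomic coordinates are reported. Members of near-identical gene families can share probes, and their values are uncertain to that extent.

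Intensities were converted to log2(value + 1). Fold changes are therefore on that scale. For each of 19938 genes the probe set with the highest mean was kept, and genes above the 30th percentile of mean log2 value (6.29) were tested, 13956 in all. Of the changed genes, 49 had another probe set above the filter; in 31 of them it was past the threshold the same way, and in 0 the other way. Knockout was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom per gene). P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors and 95% intervals are those of the moderated fit. Unless another test is named, every adjusted p is from limma. Where an array was left out, the adjusted p comes from the fit to the remaining arrays.

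The comparison, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined, apart from alternatives added later. Those were a fit with no pooling of variances and counts with the macrophage markers and small nucleolar RNAs left out. The rule takes Cyld, up to 12 higher and 12 lower genes with the largest absolute log2 fold change among those past the threshold whose arrays do not overlap between groups, up to 4 members of each process list and the 3 brightest members of each marker list. Predicted genes, unnamed clones, receptor segments and small RNAs were not eligible among the 12. The 16 process lists covered Treg core, effector and resting genes, NF-kB, TGF-beta and Wnt pathways, immediate early genes, proliferation, helper cytokines, homing, interferon response, cholesterol synthesis, glycolysis, cell death, linear ubiquitin and CYLD partners, and T cell receptor signalling. The 10 marker lists covered B, plasma, CD8 T and NK cells, macrophages, dendritic cells, granulocytes, erythroid cells, platelets and stroma. Lists with at least 3 tested members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted within the 16 process lists and within the marker lists. With an estimated correlation, and with fry, 0 of the 16 process lists were past the threshold. With an estimated correlation camera uses the 2 residual degrees of freedom, so a small p is hard to reach. Granzymes, a family chosen later, had an estimated correlation of -0.216, yet camera's unadjusted p went from 1.70e-07 to 0.0337. Failing that test therefore does not show that correlation between genes made a shift.

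Over the tested genes the 2 wild-type arrays correlated at r = 0.985 and the 2 knockout arrays at 0.974, and arrays of different groups at 0.948 to 0.960; these are correlations across genes, which are not independent replicates. The SD of the log2 difference between arrays was 0.206 within wild type, 0.269 within the knockout and 0.326 to 0.381 between groups. The first principal component held 64.5% of the variance and separated the groups, and the second, with 22.4%, lay mainly between the knockout replicates.

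The test was tried on simulated data for this comparison, with 200 of 13956 genes changed in each of 5 runs. It recovered 49.3% of the genes changed 1.5-fold, 99.4% of those changed 2-fold and 100% of those changed 4-fold, with 6.4 false calls per run on average. These rates hold for the simulated data and were not measured on the real calls. Alternatives covered the filter, the scaling between arrays, the pseudocount, the variance model, array weights, the choice of probe set, the replicate number as a block, thresholds, list tests and leaving out each array.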

Results

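Gene expression was measured on 4 Affymetrix Mouse Gene 1.0 ST arrays, 2 of wild-type and 2 of CYLD-knockout regulatory T (Treg) cells of C57BL/6 mice aged 6 to 8 weeks. Treg cells are CD4 T cells that depend on the transcription factor Foxp3 and restrain immune responses. CYLD is a deubiquitinase that removes lysine-63-linked and linear ubiquitin chains and thereby limits NF-kB signalling. In the knockout mice a floxed Cyld gene was removed by a Cre recombinase expressed from Foxp3 together with yellow fluorescent protein (YFP), and YFP-positive cells were sorted by flow cytometry. The labels give the tissue both as spleen with lymph nodes and as spleen alone, so the origin of the cells is settled only as far as the spleen. The deposited table held 35557 probe sets, with median intensities of 101 and 105 on the wild-type arrays and 103 and 99.0 on the knockout arrays. The number of arrays, 2 per group, limits the precision. Nothing in the labels says that replicates came from separate mice. The p-values thus measure only the spread between these samples, pooled over all genes, which may be technical within wild type. The knockout samples differed from each other in Y-linked genes and Xist, given with the proliferation genes. That argues against their being repeats of 1 sample.

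The comparison asks which transcripts differ between Treg cells without and with CYLD. In the knockout cells 15 of 27 effector Treg genes, 12 of 28 NF-kB target genes and 24 of 27 proliferation genes were higher, and 15 of 17 resting Treg genes and 10 of 15 macrophage markers were lower. These lists passed limma's camera test at a preset correlation between genes. With an estimated correlation, or with the rotation test fry, 0 process lists passed, and the macrophage list, with 1 member higher, had an adjusted p = 0.66 with an estimated correlation and 0.343 with fry. The estimated-correlation test has only 2 residual degrees of freedom, so failing it does not show that correlation made these shifts. Among the 12 largest rises were the chemokine genes Ccl5 and Ccl3, with Ccl5 going from an intensity of 472 ± 31.9 in wild type to 2825 ± 266 in the knockout and Ccl3 from 60.9 ± 2.71 to 474 ± 84.9 (mean ± SD, n = 2). Among the genes that fell, Gpr83, a G protein-coupled receptor typical of Treg cells, went from 1432 ± 34.3 to 364 ± 69.4. Of 13956 genes tested with limma at an adjusted p under 0.05, 669 were higher and 488 lower in the knockout, 8.29% of the genes in all. The change reached 2-fold in 110 of the higher and 45 of the lower genes, and the smallest change called was 1.40-fold.

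These calls rest on a variance pooled over all genes. The estimated prior degrees of freedom were infinite, so every log2 fold change carries the same standard error of 0.17, and the same fit with no such pooling, chosen after seeing the data, called 0 genes, with 1813 at an unadjusted p under 0.05 and a smallest adjusted p of 0.208. Leaving out 1 array also moved the counts, to 289 higher and 118 lower genes without wild-type replicate 1, 254 and 181 without wild-type replicate 2, and 919 and 767 without knockout replicate 1.

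Cyld itself was lower in both knockout samples. Its only probe set read 524 and 502 on the wild-type arrays and 284 and 218 on the knockout arrays, 48.6% of the wild-type level. The log2 fold change was -1.04 ± 0.17 (SE, limma adjusted p = 8.89e-08), the 36th largest fall. The labels do not say which part of the gene was removed, so this probe set may lie partly or wholly outside the deleted part, and a residual signal does not measure deletion.

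The 12 genes with the largest rise were Kcnip3, Scin, Tex35, Ccl3, Tm4sf5, Car1, Pnkd, Aoc1, Dscam, Ccl5, Gzmk and Il1r2. Kcnip3, which encodes a calcium-binding protein, rose by a log2 fold change of 3.74, from 67.2 ± 0.752 to 975 ± 497, with knockout values of 624 and 1326. Scin, an actin-severing protein, rose from 54.2 ± 3.40 to 538 ± 102 (log2 fold change 3.27). Gzmk, a granzyme of cytotoxic and effector T cells, rose from 116 ± 4.53 to 690.5 ± 21.1 (log2 fold change 2.56). Il1r2, the decoy receptor for interleukin-1, rose from 306 ± 7.36 to 1666 ± 115 (log2 fold change 2.44). Adjusted p-values of the 12 genes in limma ran from 1.27e-102 for Kcnip3 to 1.33e-43 for Il1r2. Such values follow from the pooled standard error and are not a measure of replication, which is 2 arrays per group. Several of these genes read close to the lower end of the intensity scale in wild type, where background in the signal understates the fold.

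The 12 genes with the largest fall were Gpr83, Sh3bgrl2, Flicr, Prg4, Usp18, C1qb, Sirpa, Tlr7, Gfra2, Slc40a1, Spic and Il6ra. Flicr, a long noncoding RNA transcribed next to Foxp3, fell from 491 ± 23.1 to 136 ± 7.19 (log2 fold change -1.85). Usp18, which removes the ubiquitin-like protein ISG15 and damps interferon signalling, fell from 795 ± 10.3 to 281 ± 93.5 (log2 fold change -1.54). Il6ra, the interleukin-6 receptor alpha chain, fell from 1161 ± 59.2 to 454 ± 42.0 (log2 fold change -1.35). C1qb, Slc40a1 and Spic are known for their expression in splenic macrophages; Spic fell from 156 ± 8.47 to 60.3 ± 9.82. Limma adjusted p-values ran from 9.95e-29 for Gpr83 to 3.41e-13 for Il6ra.

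**Figure D1:**
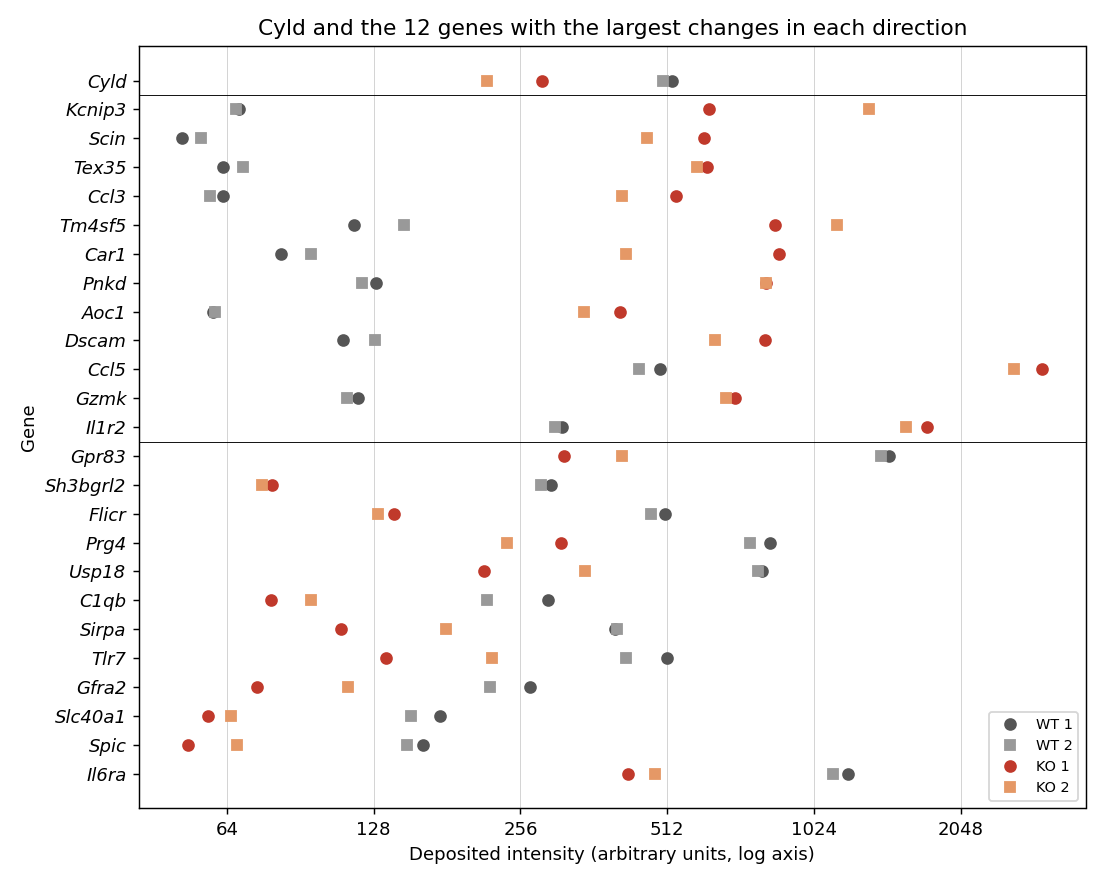
Deposited intensity on a log axis (arbitrary units) of Cyld, of the 12 genes with the largest rise and of the 12 with the largest fall; each point is 1 array, with wild type in grey and knockout in red and orange. For every gene drawn, both knockout points lie on the same side of both wild-type points, as for Ccl5, at 494 and 449 in wild type and 3013 and 2637 in the knockout.

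Effector Treg genes that changed were all higher. Of 27 tested members of this list, 15 were higher and 0 lower, 19 and 0 when adjusted over the list alone, and the mean log2 fold change was 0.55. Itgae, the integrin alpha E chain, rose from 737 ± 29.1 to 1713 ± 259. Ccr8, a chemokine receptor of activated Treg cells, rose from 400.0 ± 15.3 to 914 ± 119, and Havcr2, which encodes the inhibitory receptor TIM-3, from 116 ± 10.9 to 268 ± 0.586. Cxcr3, the receptor for Cxcl10, rose from 653 ± 11.1 to 1211 ± 27.1. Il10 and Icos, chosen after their values were seen, had log2 fold changes of -0.22 and -0.10 and did not pass the test. Limma's camera gave the list an adjusted p = 1.34e-15 with its preset correlation between genes and an adjusted p = 0.50 with an estimated correlation. Without wild-type replicate 1, 10 members were higher, and without wild-type replicate 2, 7.

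Most resting Treg genes fell. Of 17 tested members, 15 were lower and 1 was higher, the same counts as when adjusted over the list alone, with a mean log2 fold change of -0.78. Actn1, an actin crosslinker, fell from 1484 ± 5.89 to 588 ± 53.9, Igfbp4 from 695 ± 25.6 to 324 ± 56.1 and Ccr7, which guides T cells into lymph nodes, from 2637 ± 46.4 to 1341 ± 237. The member that was higher was Il7r, the interleukin-7 receptor, with a log2 fold change of 0.69, named after its value was seen; 0 members were higher without either wild-type array. Camera gave an adjusted p = 3.75e-20, and an adjusted p = 0.50 with an estimated correlation.

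NF-kB target genes that changed were all higher. Of 28 tested members, 12 were higher and 0 lower, 15 and 3 when adjusted over the list alone, with a mean log2 fold change of 0.45. Besides Ccl5, Cxcl10, a chemokine also induced by interferons, rose from 238 ± 3.42 to 763 ± 13.7. Nfkb2, a subunit of the noncanonical pathway, rose from 444 ± 59.6 to 914 ± 42.2, and Nfkbia, the inhibitor IkB alpha, read 866 and 897 in wild type and 1728 and 1635 in the knockout. Camera gave an adjusted p = 4.96e-11, and an adjusted p = 0.50 with an estimated correlation. Without wild-type replicate 1 and without wild-type replicate 2, 7 and 6 members were higher, and 1 was lower without knockout replicate 1. In the list of linear ubiquitin enzymes and CYLD partners, 0 of 23 tested members were higher and 2 were lower, 2 and 2 when adjusted over the list alone. The lower ones were Usp18 and the kinase gene Ikbkb (log2 fold change -0.66), whose adjusted p was 0.169 without wild-type replicate 1 and 0.0723 without wild-type replicate 2, where 1 member stayed lower each time; 3 members were higher without knockout replicate 2. Tnfaip3, which encodes the deubiquitinase A20, read 984 and 1017 in wild type and 1690 and 1137 in the knockout and did not pass (log2 fold change 0.47, limma adjusted p = 0.0620). Tnfaip3 did pass with quantile normalization (adjusted p = 0.0382), with 16 added before the logarithm (0.0349), with an intensity trend (0.00391) and without knockout replicate 2 (0.00149).

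Most proliferation genes rose. Of 27 tested members, 24 were higher and 0 lower, 25 and 0 when adjusted over the list alone, with a mean log2 fold change of 0.76. Mki67, the proliferation marker Ki-67, rose from 325 ± 54.9 to 712.5 ± 105. Ccnb2, cyclin B2, rose from 527 ± 37.8 to 1206 ± 504 and Rrm2, a ribonucleotide reductase subunit, from 328 ± 24.7 to 705 ± 218. The knockout replicates differed: the list's mean log2 difference from the wild-type mean was 0.43 in replicate 1 and 1.09 in replicate 2. Ccna2, cyclin A2, read 607 and 1264 on them and was not past the threshold without knockout replicate 2 (limma adjusted p = 0.0886), and 7 members were higher without that array, 16 without wild-type replicate 1 and 15 without wild-type replicate 2. Camera gave the list an adjusted p = 1.58e-28, and an adjusted p = 0.50 with an estimated correlation. The same array stood apart in sex-linked genes, looked up after the data were seen. Y-linked Kdm5d, Uty and Eif2s3y read 127, 132 and 98.9 on knockout replicate 2 and 268, 283 and 221 on knockout replicate 1. Xist read 2321 on replicate 2 and 1630 on replicate 1. Between the groups limma called Kdm5d and Eif2s3y lower (adjusted p = 0.0160 and 0.00242) and Xist higher (0.0291), but not Uty (0.545). The calls between genotypes thus include sex-linked genes. In wild type Kdm5d read 271 and 275 and Eif2s3y 253 and 219, and knockout replicate 1 was close to those levels. Their calls rest on knockout replicate 2 alone, with a standard error pooled over all genes, and show no difference shared by the knockout samples. For Xist, at 1306 and 1403 in wild type, a different mix of sexes cannot be told apart from genotype.

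The list of chemokine receptors and homing molecules had 7 members higher and 2 lower of 23 tested, also when adjusted over the list alone, with a mean log2 fold change of 0.20. Ccr6 rose from 252 ± 23.7 to 571 ± 15.7 alongside Ccr8 and Itgae, and Ccr7 fell. This list shares 6 members with the effector Treg list and 2 with the resting Treg list. Camera gave an adjusted p = 0.0126, and an adjusted p = 0.53 with an estimated correlation; the adjusted p was 0.0639 without wild-type replicate 2 and 0.0678 without knockout replicate 1.

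Among Wnt and beta-catenin target genes, 1 was higher and 4 were lower of 10 tested, also when adjusted over the list alone, with a mean log2 fold change of -0.29. The transcription factor gene Myc fell, reading 878 and 847 in wild type and 425 and 437 in the knockout, as did Tcf7l2 and Znrf3, both with a log2 fold change of -0.98. Rnf43, which like Znrf3 encodes a ubiquitin ligase that removes Wnt receptors, rose by 0.92. Camera gave this list an adjusted p = 0.0126, an adjusted p = 0.53 with an estimated correlation, an adjusted p = 0.113 without knockout replicate 1 and an adjusted p = 0.0585 over genes above the median intensity.

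Interferon response genes that changed were all lower. Of 24 tested members, 0 were higher and 5 lower, 2 and 8 when adjusted over the list alone, with a mean log2 fold change of -0.27. Besides Usp18, Ifit3 fell from 390 ± 33.7 to 223 ± 70.6, Ifit1 from 855 ± 16.5 to 497 ± 174 and Oas2 from 123 ± 14.8 to 79.3 ± 3.60. Camera gave an adjusted p = 5.32e-04, and an adjusted p = 0.53 with an estimated correlation. Without knockout replicate 1 the list had an adjusted p = 0.149, with a mean log2 fold change of -0.16, 1 member higher and 3 lower, and Ifit1 an adjusted p = 0.0688. There were 10 lower members and a mean of -0.39 without knockout replicate 2, and 3 lower members without wild-type replicate 1, where Oas2 had an adjusted p = 0.386.

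The Treg core signature did not pass the list test (camera adjusted p = 0.583). Of its 19 tested members, 2 were higher and 2 lower, 3 and 3 when adjusted over the list alone. Gpr83 and Izumo1r, the folate receptor 4 gene, fell, the second by a log2 fold change of -0.56, and Itgb8 and Tnfrsf1b rose by 0.80 and 0.50. Foxp3 and Il2ra, named after their values were seen, had log2 fold changes of -0.26 and -0.45 and did not pass (limma adjusted p = 0.395 and 0.0831). Izumo1r had an adjusted p of 0.431 without wild-type replicate 1 and 0.128 without wild-type replicate 2. Tnfrsf1b had 0.349 and 0.361 without those arrays, 0.0873 without knockout replicate 1 and 0.0572 with the replicate number as a block.

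Helper T cell cytokines and regulators had 3 higher and 0 lower of 13 tested members, also when adjusted over the list alone, and a camera adjusted p of 0.0712. Il4 rose from 96.4 ± 0.125 to 177 ± 25.3, Tbx21, which encodes T-bet, from 170 ± 16.9 to 268 ± 48.1 and Ifng from 151 ± 3.11 to 237 ± 60.5. The list had an adjusted p of 0.0455 without wild-type replicate 1 and 0.0153 without knockout replicate 2. Tbx21 had an adjusted p of 0.261 without wild-type replicate 2 and 0.111 without knockout replicate 2, and Ifng 0.129, 0.167 and 0.159 without wild-type replicate 1, wild-type replicate 2 and knockout replicate 1. Without wild-type replicate 2, 1 member was higher.

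In the TGF-beta and Smad list, 2 of 22 tested members were higher and 1 lower, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.994). Itgae and the inhibitor gene Id2 rose, Id2 by a log2 fold change of 0.59, and the related Id3 fell by a log2 fold change of -0.75. Id2 had an adjusted p between 0.0545 and 0.222 without either wild-type array or knockout replicate 1, and Id3 had 0.160 without wild-type replicate 1. Among immediate early genes 1 of 24 was higher and 0 lower, also over the list alone (camera adjusted p = 0.583). This was Nr4a2, which rose from 260 ± 18.2 to 598 ± 135, while 4 members were lower without knockout replicate 1 and 3 were higher without knockout replicate 2. In the cell death list 1 of 21 was higher and 2 were lower, 2 and 4 when adjusted over the list alone (camera adjusted p = 0.115). Bcl2 fell from 1312 ± 71.1 to 708 ± 73.3 and Bcl2l11, the pro-apoptotic BIM gene, from 512 ± 6.90 to 301 ± 8.48. Pmaip1, the NOXA gene, rose by a log2 fold change of 0.58 and had adjusted p-values of 0.110, 0.363 and 0.293 without wild-type replicate 1, wild-type replicate 2 and knockout replicate 1.

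Of 16 tested glycolysis genes, 1 was higher, Tpi1 with a log2 fold change of 0.58, and 1 lower, Pdk1 with -0.80, also over the list alone (camera adjusted p = 0.639). Tpi1 had adjusted p-values of 0.199 and 0.224 without wild-type replicates 1 and 2, and Pdk1 had 0.142 without wild-type replicate 1; 2 members were lower without knockout replicate 1. Of 24 T cell receptor signalling genes, 0 were higher and 1 was lower, also over the list alone (camera adjusted p = 0.103). This was Prkcq, the kinase PKC theta, with a log2 fold change of -0.60 and adjusted p-values of 0.272, 0.124 and 0.0846 without wild-type replicate 1, wild-type replicate 2 and knockout replicate 2. The list itself had an adjusted p of 0.0420 without wild-type replicate 2 and 0.0285 with an intensity trend in the variances, and 1 member was higher and 2 were lower without knockout replicate 1, and 1 and 1 without knockout replicate 2. In limma, 0 of 17 cholesterol synthesis genes were past the threshold, also over the list alone (camera adjusted p = 0.671). Dhcr7 and Hmgcs1 had log2 fold changes of -0.41 and -0.37, with unadjusted p-values of 0.0158 and 0.0284.

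**Figure D2:**
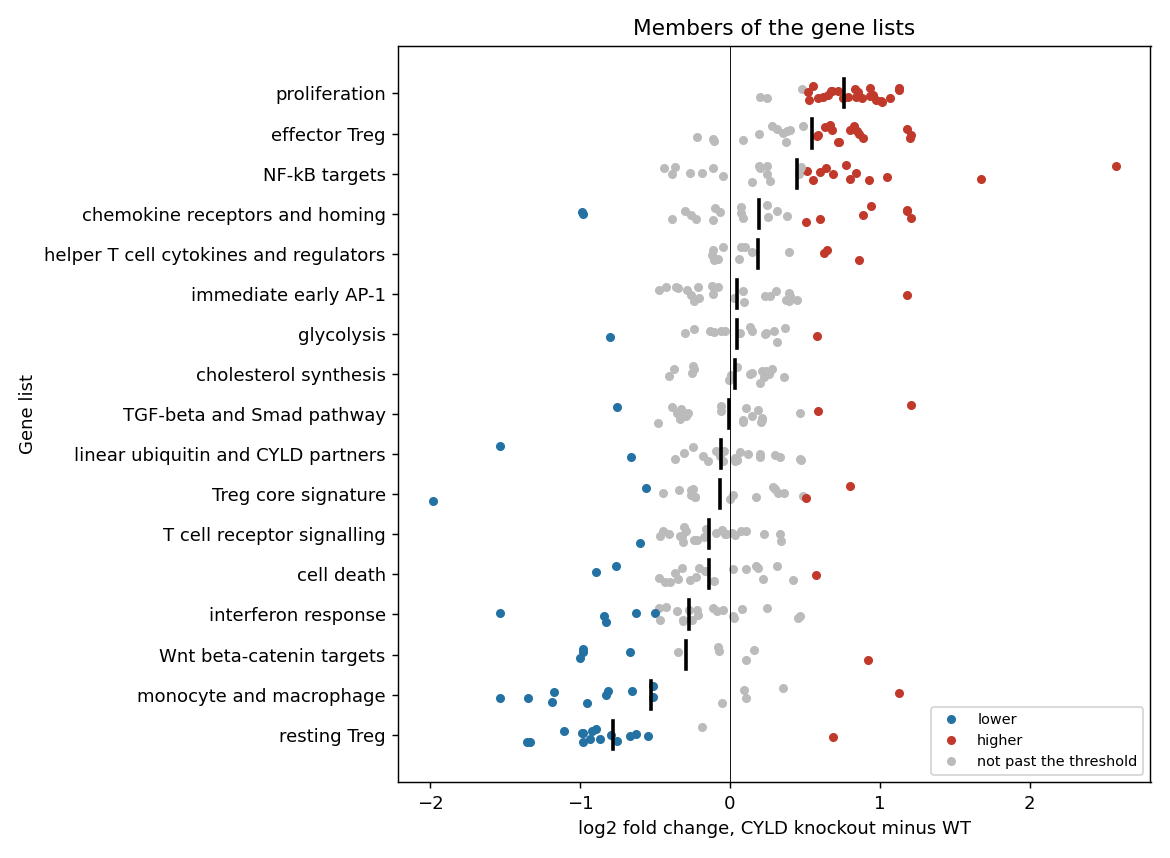
Log2 fold change, knockout minus wild type, of each tested member (points, with random vertical scatter) of the 16 process lists and the macrophage marker list; the black bar is the mean of the list and colours show limma calls. The mean lies at 0.76 for proliferation, 0.55 for effector Treg and -0.78 for resting Treg genes.

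Markers of other cell types were examined because a sort can hold other cells. Of 15 tested monocyte and macrophage markers, 10 were lower and 1 higher, 10 and 2 when adjusted over the list alone, with a mean log2 fold change of -0.53. C1qb fell from 255 ± 52.1 to 87.0 ± 11.7; the one that rose was Cybb, an NADPH oxidase subunit, from 486 ± 46.7 to 1064 ± 108. Ctss and Cst3, the other bright members, had log2 fold changes of 0.35 and 0.10 and did not pass, though Ctss did with an intensity trend (adjusted p = 0.0253). Camera gave the list an adjusted p = 1.60e-08, and an adjusted p = 0.66 with an estimated correlation. The fall accompanied that of resting Treg genes, of interferon response genes and of Slc40a1, Spic, Sirpa and Tlr7. Against the wild-type mean, macrophage markers had a mean log2 difference of -0.69 in knockout replicate 1 and -0.36 in replicate 2. Interferon response genes had -0.39 and -0.16 on the same arrays.

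For the 7 other marker lists that could be tested, camera adjusted p-values were above the threshold. The NK cell list had the lowest, 0.132, with 1 of 4 members higher, also over the list alone. This was Eomes, a transcription factor also used by T cells, which rose from 104 ± 6.90 to 320 ± 32.3, while Prf1 and Klre1 had log2 fold changes of -0.02 and -0.18. The CD8 genes Cd8a and Cd8b1, too few for the list test, had 0.10 and 0.22. Car2, the only tested erythroid marker of a list of 10 and too few for the list test, rose by 1.44. Car1, a related gene outside that list, rose by 2.76. Whether erythroid cells in the sorts bear on either was not tested. In limma 0 B cell markers of 7 were called, 0 and 2 when adjusted over the list alone, with Cd79b and Bank1 both at -0.45 (camera adjusted p = 0.906); Cd79b had an adjusted p of 0.0494 without knockout replicate 1. The lists of 4 plasma cell, 8 dendritic cell, 3 granulocyte and 3 platelet markers had 0 calls, also over the list alone, with camera adjusted p-values of 0.733, 0.906, 0.774 and 0.774; 2 plasma cell markers and 1 dendritic cell marker were higher without knockout replicate 1. Of 8 stromal and endothelial markers, Pecam1 was lower (log2 fold change -0.56), also over the list alone, and had adjusted p-values of 0.544, 0.0933 and 0.0750 without wild-type replicate 1, wild-type replicate 2 and knockout replicate 2 (list camera adjusted p = 0.774).

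Small nucleolar RNAs were chosen as a group after the data were seen. Of 43 tested, 0 were higher, 18 lower and 25 not past the threshold (camera adjusted p = 2.42e-13, adjusted p = 0.298 with an estimated correlation and 0.137 with fry), with a mean log2 fold change of -0.44 and median log2 intensities of 7.96 and 8.05 on the wild-type and 7.50 and 7.36 on the knockout arrays. With these and the macrophage markers left out, 668 genes were higher and 459 lower.

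**Figure D3:**
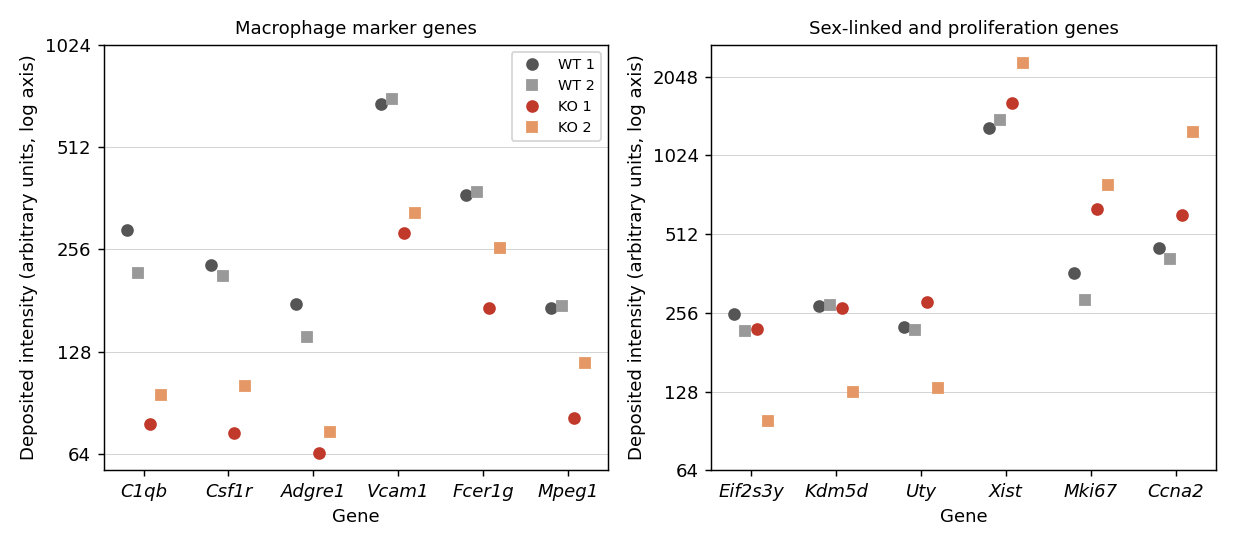
Deposited intensity on log axes (arbitrary units) of 6 macrophage markers chosen among those that fell (left) and of 4 sex-linked and 2 proliferation genes (right); each point is 1 array, with wild type in grey and knockout in red and orange. The macrophage markers shown are lower on both knockout arrays, and Kdm5d reads 127 on knockout replicate 2 against 271, 275 and 268 on the other arrays.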

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

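The test of probe sets outside the gene comparison and the count over splits of the arrays were chosen after the gene results were seen. Among the 8413 tested probe sets with no listed symbol or with several symbols, 85 were higher in the knockout and 203 lower in limma. Here the filter and the adjustment ran over all probe sets. The share called was smaller than the 8.29% in the gene comparison. They were looked at because they lie in data that the gene comparison leaves out. No explanation of them was tested.

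The 4 arrays can be split into groups of 2 in 3 ways, too few for a share under 0.05. The real split gave 1157 changed genes and was the 1 split with as many. The highest of the other splits gave 0 in limma, with 56 genes at an unadjusted p under 0.05. Each other split puts 1 knockout and 1 wild-type array in each group, so the knockout difference enters the pooled variance. Few calls were therefore bound to follow, and the count over splits lends the 1157 calls no support.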

How the results depend on the processing

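The fits with no pooling of variances and with the macrophage markers and small nucleolar RNAs left out were chosen after seeing the data. Cyld stayed lower and past the threshold under every alternative with pooled variances, with log2 fold changes from -1.23 to -0.85, the ends being the fits without knockout replicates 1 and 2. No result changed sign past a threshold. Leaving out 1 array gave 254 to 919 higher and 118 to 767 lower genes and 4 to 8 process lists past the threshold; the lone array of a group was then taken to vary like the other group. Why the counts moved was not tested. At an unadjusted p under 0.05 there were 1364 higher and 1424 lower genes, and 110 and 45 changed at least 2-fold with arrays that did not overlap, with no test. With no pooling of variances 0 were higher and 0 lower, with 1813 at an unadjusted p under 0.05. Of the process lists, 0 passed with an estimated correlation and 0 with fry, against 7 in the camera test at its preset correlation. Quantile normalization gave 762 and 462 genes and median centring 713 and 408. The replicate numbers are shared by the groups but not said to pair mice: the differences between replicates 1 and 2 correlated at -0.0920 between groups, across genes. With the replicate number as a block, 603 genes were higher and 428 lower, and 7 lists passed. Of 66 named genes past the threshold besides Cyld, 51 kept their call and direction under every alternative with pooled variances and 15 lost the call under at least 1; with no pooling all of them lost it. Robust variances and separate probe sets were not run for the lists. Signal over background limits the folds of dim genes.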

Other observations

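The 12 gene families below and the tests of explanations were chosen after the gene results had been seen; only the test on 8 further macrophage genes was set before their values were looked at. Of 23 chemokine ligands 6 were higher, 0 lower and 17 not past the threshold, with a mean log2 fold change of 0.55 and a median of 0.14. Besides Ccl3, Ccl5 and Cxcl10, these were Ccl1 (2.42), Xcl1 (2.08) and Cxcl11 (0.56). Of 4 granzymes, Gzmk and Gzmb were higher, Gzmb by 0.63, and of 6 caspases the inflammatory Casp4 (1.74) and Casp1 (1.16). MHC class II genes had 3 of 8 higher, with Cd74 at 1.81, H2-DMa at 0.74 and H2-Eb1 at 0.57, and 1 lower, H2-Ob at -1.03. Of 38 histone genes 7 were higher and 0 lower, led by H1f5 at 0.90, with a mean shift of 0.11 in knockout replicate 1 and 0.34 in replicate 2, the array that stood apart in proliferation and Y-linked genes. Camera adjusted p-values over the 12 families were 2.21e-13 for chemokine ligands, 5.11e-07 for granzymes, 0.0192 for caspases, 0.00305 for MHC class II and 2.17e-04 for histones, and with an estimated correlation the adjusted p-values were 0.202, 0.202, 0.298, 0.332 and 0.420. For these 5 families the sign of the mean was the same under quantile normalization and median centring; the caspase median, -0.15, lies on the other side of 0 from its mean of 0.33.

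Of 26 interleukin receptors 5 were higher and 4 lower, and 5 and 2 with median centring (camera adjusted p = 0.146). Il13ra1 rose by 1.47 and Il1r2 by 2.44, while Il6ra fell by 1.35 and its signalling partner Il6st by 0.89. Of 12 Kruppel-like factors Klf12 rose by 0.98, and Klf2, Klf3 and Klf7 had -0.62, -0.58 and -0.76 (camera adjusted p = 0.101). Of 18 TNF receptor family genes 2 were higher and 3 lower, and of 22 integrins 3 and 2, with Itga6 at -1.02; camera adjusted p-values were 0.981 and 0.599, and the TNF receptor family mean was -0.01 as deposited and 0.03 with quantile normalization. S1pr1 was the lower gene of 5 sphingosine-1-phosphate receptors (list adjusted p = 0.386). In limma 0 of 53 ribosomal protein genes were called, with a mean log2 fold change of -0.28 (camera adjusted p = 5.11e-07, and 0.298 with an estimated correlation). For small nucleolar RNAs, camera gave an adjusted p = 2.42e-13, and 0.298 with an estimated correlation. Over the 12 families fry gave adjusted p-values of 0.0222 for granzymes and 0.0459 for each of chemokine ligands, ribosomal proteins and Kruppel-like factors, and 0.0945 or more for the others. Because the families were chosen with the gene results in view, their p-values lend no support to a shift. Nor can they be ranked against the lists fixed beforehand, which did not pass fry.

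Of 15 macrophage markers 10 were lower and 1 was higher in the knockout (list adjusted p = 0.66 with an estimated correlation and 0.343 with fry). Array scale or a background shared by genes of like intensity is argued against as the whole cause, since the mean log2 fold change stayed at -0.50 with quantile normalization and 0% of 10000 random lists matched on intensity had a mean as low; neither test bears on members moving together. More macrophage RNA in the wild-type sorts may account for the fall. A set of 8 splenic macrophage genes not looked at before had a median log2 fold change of -0.48. Its 95% bootstrap interval over the genes, -0.86 to -0.09, shows spread between genes on the same arrays and not between replicates. Limma called Mrc1, Treml4, Fcna and Hpgd lower and Axl higher (1.02), while Itgad, Siglec1 and Slco2b1 did not pass. None of the 15 markers is in another list fixed beforehand, but how many of them Treg cells express was not measured. The bright Ctss, Cst3 and Cybb did not fall. A YFP gate is meant to exclude macrophages, but the purity of the sorts was not measured here. Fewer macrophages in the knockout mice, and a lower level of these genes in knockout Treg cells, stay open as well and were not tested.

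Of 27 effector Treg genes 15 were higher and of 17 resting Treg genes 15 were lower and 1 higher (both lists adjusted p = 0.50 with an estimated correlation and 0.108 with fry), and a single knockout array is argued against by the effector list's mean shift of at least 0.48 without either, with 13 members higher without replicate 1 and 16 without replicate 2. CD8 T or NK cells in the knockout sorts, which a gate on Foxp3-driven YFP is meant to exclude, cannot be told apart from a change in Treg cells. Cd8a, Cd8b1, Klrb1c, Klre1 and Prf1 had a median log2 fold change of -0.0249. All except Cd8b1 read only 86.3 to 122 in wild type, near the array medians, and the upper 95% limit for Cd8b1 was 0.55. Conventional T cells lacking Foxp3 are argued against as the whole cause of the resting gene fall, because the lower 95% limit for Foxp3, -0.59, lies above the median of that list, -0.89. For the effector genes such cells, which the YFP gate is also meant to exclude, cannot be told apart from a change in Treg cells. Foxp3 had -0.26 (95% interval -0.59 to 0.07), which leaves room for a small share of them. Cd40lg and Il2, predicted to rise with such cells, had -0.39 (95% interval -0.72 to -0.06) and 0.07. Il2 read 117 and 122 in wild type and 113 and 140 in the knockout, near the array medians, where a small rise could be missed. A hypothesis that stays open is that loss of CYLD may raise the share of effector Treg cells or the level of effector genes per cell. Bulk arrays do not separate these, and single-cell profiles or separately sorted effector and resting Treg cells would.

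Proliferation genes were higher in knockout replicate 2 than in replicate 1, and Y-linked genes lower. Replicate 2 alone is argued against as the only source of the rise, since without it the mean shift was 0.43, against 0.76 with it. The rule for this, set after the data were seen, asked for more than 1/3 of the shift. For the effector list the rule asked for more than 2/3, which the proliferation shift would not meet. Over all arrays the proliferation list had an adjusted p of 0.50 in camera with an estimated correlation and 0.266 with fry. A different mix of male and female mice in that sample may account for its Y-linked genes, which were lower by a mean log2 difference of -1.10 against replicate 1, with Xist higher by 0.51. The labels give no sex, and whether it bears on the proliferation genes or on other calls between the groups was not tested.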
